A study of Drosophila melanogaster with 9 samples.

How the data were processed

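Total RNA from ovaries of 3 fly lines, with 3 libraries per line, was depleted of ribosomal RNA, and paired-end libraries were prepared and sequenced, per the labels' protocols. Salmon 1.3.0, R 3.6.3, DESeq, DESeq2 1.25.10 and the genome build BDGP6 are named in the submitters' processing notes, without their roles or order. The annotation release, read trimming, strand setting and filters on genes are not given in the sources used here. Whether the salmon estimates were summed per gene is likewise not stated.

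One table of the whole series was used. Its mean normalized count per gene is a signal value (gene counts divided by size factors and averaged over libraries) that the authors made before deposit, by the meaning DESeq2 gives a column of that name. The log2 fold changes of each mutant line over the P-element line and the adjusted p-values were computed by the authors and deposited as they stand, per the file headers. The headers do not state the base of the logarithm, and base 2, which DESeq2 reports, was assumed. The median absolute log2 change of tested genes was 0.03 in M6stop and 0.11 in F9ΔNLS. Whether fold changes were shrunk is not stated, but calls such as that of His2B:CG33902 in M6stop, with a value of 0.003 and a DESeq2 adjusted p of 6.1e-06 at a mean of 31.7 normalized counts, are hard to explain without it. Shrinkage pulls uncertain genes toward 0 and makes sizes differ between the comparisons, so listed values near 0 were not read as small changes where the adjusted p passed, and rankings and limits on fold change depend on it. An adjusted p was given for 10662 of 17199 genes, the same genes in both comparisons, and a fold change for 14232. Genes without an adjusted p were left out of every test. The adjustment method is not stated.

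The table also holds 9 columns of per-library values whose names are codes that match no sample label. They could not be tied to lines without guessing from their order or values, so no result uses them. For that reason the models planned before the data were examined (edgeR's quasi-likelihood test, or limma for normalized values) were not fitted, and no value per library, standard deviation, replicate check or direct test between the mutant lines is given. The depth of single libraries is not analysed here, and no interval or floor that needs it is given. The comparison columns name the lines in short form, and the P-element line was taken as the control from the growth protocol.

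From this table, genes with an adjusted p under 0.05 were counted by direction. Gene identifiers were matched to Ensembl release 115 (BDGP6.54). Of the 17199 identifiers 17063 had a position there, and all 17030 of these that the table places on a chromosome had the same chromosome in both. Positions are from that annotation. The 29 gene lists were fixed before the data were examined, and 10 of their entries were not found by name. Each list was tested for an excess of genes that rose, and of genes that fell, by one-sided Fisher's exact tests against all other tested genes, with Benjamini-Hochberg adjustment over the 58 tests per comparison. These tests took the place of the planned gene set test, which needs library values, and were chosen after the table was seen. Genes of a list are co-regulated, so the p-values are too small, and no correlation between genes could be estimated. As an alternative, the median log2 change of each list was placed among 10000 random lists matched on mean count in 20 bins. It is called a permutation test below, but genes were drawn at random and no library labels were permuted. The draws treat genes as independent, so these p-values are too small for co-regulated lists as well. For counts adjusted over the list alone, unadjusted p-values were rebuilt from the adjusted ones on the assumption of a Benjamini-Hochberg adjustment over the 10662 genes. Tied values (77.6% of genes in M6stop, 51.7% in F9ΔNLS) give an upper bound of p, so these counts are minimums.

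Genes were named by a rule set before the data were examined: Pcif1, w, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalized counts, up to 4 genes per list with the smallest p, and the 10 genes with the largest change in both lines. The rule's condition that libraries of the 2 groups do not overlap could not be applied, and the mean over all libraries took the place of the higher group's mean. Vm26Ac, Vm32E, fs(1)N, Cp15, Cp36, Cp38, Cyp12d1-p, His4:CG33881, the Orc, Mcm, eIF and Vha genes, the ribosomal RNA genes and the genes said to be chosen later fall outside the rule and were named after their values were seen. Calls within 5 Mb of Pcif1 were compared with calls elsewhere by a two-sided Fisher's exact test over the tested genes with a position. Shared controls were simulated with normal values of equal spread in 3 unchanged groups, 1000 times.

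The list, window and p-rebuilding steps were tested on simulated data for the 10662 tested genes with 200 changed genes, 20 times. The changed list was found in 20 of 20 draws, and 0 of 1120 tests of unchanged lists passed. The rebuilt p was at or above the true one for all genes and exact for 8.98% of them. Genes were simulated as independent, and every gene of the changed list was shifted. The draws therefore check the code and do not give the error rate for co-regulated lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a log2 change of at least 1, a mean of at least 1 CPM of the summed means, other thresholds of the adjusted p, protein-coding genes alone, other windows and other list tests.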

Results

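Ribosomal-RNA-depleted total RNA from fly ovaries was sequenced in 9 libraries, 3 from each of 3 Drosophila melanogaster lines. The control line, Pcif1 BG02557, carries a P-element in the first intron of Pcif1, the fly relative of the gene for a protein that binds the phosphorylated tail of RNA polymerase II. Both mutant alleles came from genome editing of the stretch of Pcif1 that encodes its nuclear localization signal. The M6stop allele has a frameshift that runs into an early stop codon, and the F9ΔNLS allele lacks the signal in frame, which leaves a protein of 829 amino acids. The labels give 3 pairs of ovaries per line, and the series' design text calls the 3 libraries of a line biological replicates. The question was which ovarian transcripts change in each mutant line against the control line.

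The values come from the authors' deposited table, which lists 17199 genes with a mean normalized count, a log2 fold change over BG02557 for each mutant and an adjusted p. An adjusted p was given for 10662 genes, and these are the genes tested. The mean normalized counts of all genes in the authors' deposited table sum to 5.07e+07, of which 64.3% fell in 47 ribosomal RNA genes and pseudogenes, and the other genes sum to 1.81e+07. The median tested gene had a mean of 570 normalized counts. No standard error was used, so the fold changes below carry no interval. The adjusted p takes the spread between libraries into account but does not measure it, and no measure of that spread is given. Some genes had a listed value close to 0 beside a very small adjusted p, which points to fold changes that were shrunk toward 0, so the values below may understate the changes, and to differing degrees between genes and lines. A gene is said to have risen or fallen where the authors' DESeq2 adjusted p was under 0.05.

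The M6stop ovaries had less Pcif1 RNA than the control ovaries, and no change was detected in the F9ΔNLS ovaries. In the authors' deposited table, Pcif1 (CG11399, FBgn0037021, 3L from 20780350 to 20786197 on the minus strand, BDGP6) fell by 2.51 on the log2 scale in M6stop, with a DESeq2 adjusted p listed as 0. The same gene had a log2 fold change of 0.02 in F9ΔNLS, with a DESeq2 adjusted p of 0.83 in the authors' deposited table. Its mean over all libraries was 3326 normalized counts in the authors' deposited table. The eye-colour gene white (w), at a mean of 32.1 normalized counts, had a log2 fold change of -0.07 in M6stop (DESeq2 adjusted p = 0.16) and one of -0.80 in F9ΔNLS (DESeq2 adjusted p = 0.030) in the authors' deposited table. It lies inside the span of kirre on the X chromosome, on the other strand, so its reads are uncertain where the genes overlap.

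In M6stop ovaries 589 genes, 5.52% of the genes tested, differed from the control line, and 371 of them (63.0%) rose. By Fisher's exact tests, genes of the respiratory chain, yolk proteins and their uptake, glutathione S-transferases and P450s as a joint list, muscle and fat body rose more often than other genes, and histone genes fell more often. The log2 change was at least 1 for 157 of the genes that rose and 49 of those that fell. The median absolute log2 change of the called genes was 0.62, and 45 calls were under 0.1.

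Detoxification enzymes had the largest rises in M6stop among genes with a mean of at least 50 normalized counts. Cyp12d1-d, a cytochrome P450, rose by 11.27 (DESeq2 adjusted p = 6.1e-05) and Cyp4p2, another one, by 8.17 (DESeq2 adjusted p = 1.0e-21) in the authors' deposited table. Cyp12d1-d has a near-identical copy, Cyp12d1-p, which had a value of 0.03 in the authors' deposited table, so the split of reads between them is uncertain. The uncharacterized genes CG4570 (5.28), CG43120 (4.36), CG2993 (4.13) and CG34109 (3.89) also rose in the authors' deposited table. The others of the top 10 in the authors' deposited table were Btnd (4.89), the hairpin RNA gene hpRNA:CR33940 (3.46), the metallothionein gene MtnC (3.32) and Ser12 (2.93), a serine protease gene. The hairpin RNA gene lies on 3L from 19486745 to 19488439 and overlaps CG32212 on the other strand, so its value is uncertain too. In F9ΔNLS, Cyp12d1-d (0.04, DESeq2 adjusted p = 0.046), Cyp4p2 (0.32, DESeq2 adjusted p = 0.027) and Btnd (0.19, DESeq2 adjusted p = 0.048) were called upward as well in the authors' deposited table. These listed values do not give the size of the changes. MtnC (0.04, DESeq2 adjusted p = 0.41) did not pass in F9ΔNLS in the authors' deposited table.

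Enzymes, surface proteins and uncharacterized genes were among the largest falls in M6stop. CG12708 (X from 15675476 to 15677737) fell by 6.56 (DESeq2 adjusted p = 2.7e-35) in the authors' deposited table. Ugt86Dc, a glycosyltransferase gene, fell by 4.25, and CG11241 fell by 4.01 in the authors' deposited table. Further falls in the authors' deposited table were those of Hayan, a protease of the melanization pathway (-2.93), dpr6, a cell-surface immunoglobulin gene (-2.69), and kirre, a cell-adhesion gene (-1.91). With Pcif1, the genes CG1909 (-2.02), CR43309 (-2.003) and CG1208 (-1.93) completed the top 10 of the authors' deposited table.

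Respiratory-chain genes rose together in M6stop. Of 73 tested oxidative phosphorylation genes, 25 rose and 0 fell (adjusted p = 4.5e-17, one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 58 list tests). The list median was 0.17 in the authors' deposited table. COX7A (0.53) and cype (0.45), both cytochrome c oxidase subunits, and the ATP synthase genes ATPsynbeta (0.34) and ATPsynC (0.28) rose in the authors' deposited table. Adjusted over the list alone, at least 43 passed upward and 0 downward. Of 13 protein-coding genes of the mitochondrial genome 2 rose in M6stop and 1 in F9ΔNLS, and mt:ND1 rose in both (0.39 and 0.38) in the authors' deposited table. Neither Fisher's exact test of this list passed, but in M6stop the list, with a median of 0.12 in the authors' deposited table, passed against random lists matched on mean count (adjusted p = 0.0017, a permutation test). Muscle genes, markers of another cell type, moved with this group: 5 of 26 rose and 0 fell (adjusted p = 0.021, Fisher's exact test), with at least 12 upward and 2 downward adjusted over the list alone. They included Mlp84B (1.06), Act57B (0.71) and TpnC73F (0.66) in the authors' deposited table.

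The 3 yolk protein genes rose in M6stop. Yp3 rose by 1.10 (DESeq2 adjusted p = 9.3e-04), Yp1 by 1.05 (DESeq2 adjusted p = 0.0039) and Yp2 by 0.83 (DESeq2 adjusted p = 0.017) in the authors' deposited table. They were the 3 rises among 6 tested genes of yolk protein and uptake (adjusted p = 0.011, Fisher's exact test), and at least 4 passed adjusted over the list alone. In F9ΔNLS 2 of the 6 rose, Yp2 (0.71) and the lipoprotein receptor gene LpR2 (0.33), in the authors' deposited table, and the list test did not pass (adjusted p = 0.53, Fisher's exact test). Yolk proteins are made in follicle cells and also in fat body, and fat-body markers rose beside them in M6stop: 4 of 19 (adjusted p = 0.036, Fisher's exact test), with at least 4 upward and 1 downward adjusted over the list alone. These were the lipoprotein genes apolpp (1.29) and Apoltp (1.67), with CG6910 (1.69) and Obp99a (0.996), in the authors' deposited table.

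Of 87 glutathione S-transferase and P450 genes, 11 rose and 4 fell in M6stop (adjusted p for rises = 0.0039, Fisher's exact test). Besides Cyp4p2, Cyp4e3 rose by 3.18 and Cyp6a2 by 2.57, and GstS1 fell by 0.57 in the authors' deposited table. Adjusted over the list alone, at least 11 passed upward and 5 downward. Against random lists matched on mean count, neither this list nor the fat-body list passed in M6stop (adjusted p = 0.13 and 0.90, random matched lists as a permutation test).

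Histone genes of the replication-dependent cluster fell in M6stop. Of 23 tested copies 5 fell and 1 was called upward (adjusted p for falls = 0.0025, Fisher's exact test). His2B:CG33868 fell by 0.50, and His3:CG33821 (-0.48) and His2A:CG33814 (-0.40) fell as well in the authors' deposited table, while His2B:CG33902, at a mean of 31.7 normalized counts, was called upward (DESeq2 adjusted p = 6.1e-06) with a listed value of 0.003 that does not give the size of its change. At least 10 copies passed downward and 1 upward adjusted over the list alone. The copies of a histone are nearly identical, so the split of reads between them is uncertain.

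No germline list passed Fisher's exact test in M6stop, although single genes changed. Of 14 egg activation and late oocyte genes 1 fell, the oocyte thioredoxin gene dhd (-0.97, DESeq2 adjusted p = 1.9e-12), in the authors' deposited table. Of 32 piRNA pathway genes 3 fell (adjusted p = 0.17, Fisher's exact test), namely rhi, which encodes a chromatin protein of piRNA source loci (-0.65), tapas (-0.23) and nxf2 (-0.23), in the authors' deposited table. Of 19 stem cell and early cyst genes 1 rose, Dad (0.40), and of 13 vitelline membrane genes 2 rose, Vm26Ab (0.84) and psd (0.63), in the authors' deposited table. Of 27 follicle cell genes 1 fell, kek1 (-0.70), and of 88 cytoplasmic ribosomal protein genes 1 fell, RpS5b (-0.28), in the authors' deposited table. Chorion genes (15 tested), oocyte axis genes (22), meiotic genes (28), proteasome genes (32) and ecdysone genes (24) had 0 calls by DESeq2 in M6stop, with at least 0, 3, 3, 3 and 2 members at an unadjusted p under 0.05. Against random lists matched on mean count, a permutation test of the list median, egg activation and late oocyte genes (median -0.07, adjusted p = 0.0074), vitelline membrane genes (0.08, adjusted p = 0.0074), proteasome genes (-0.06, adjusted p = 9.7e-04) and cytoplasmic ribosomal protein genes (-0.01, adjusted p = 0.0029) passed in M6stop, with medians from the authors' deposited table. Random lists hold independent genes, so a list of co-regulated genes can pass with a median this close to 0.

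In F9ΔNLS ovaries 1233 genes rose and 1264 fell, together 23.4% of the genes tested. Histone, late-oocyte, meiotic and vitelline membrane genes fell more often than other genes, and respiratory-chain, muscle, follicle-cell and immune genes rose more often. The median absolute log2 change of the called genes was 0.38, with 164 rises and 106 falls of at least 1, and 29 calls were under 0.1.

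A block of neighbouring proteases was among the largest rises in F9ΔNLS. CG2993 rose by 4.80 (DESeq2 adjusted p = 1.6e-113), Send1, a spermathecal endopeptidase gene, by 4.25 (DESeq2 adjusted p = 3.4e-16) and CG4570 by 4.22 in the authors' deposited table. CG17239 (3.71), Ser12 (3.24) and CG31681 (3.23) rose in the authors' deposited table and lie with Send1 between 2250431 and 2286873 on 2L. In M6stop these 4 genes rose by 2.16 to 2.93 in the authors' deposited table. The rest of the top 10 in the authors' deposited table were CG43120 (3.38), CG42342 (3.24), CG45263 (3.18) and CG34109 (3.16). Of 15 tested genes of the spermatheca and reproductive tract list, 3 rose and 4 fell in F9ΔNLS (adjusted p for falls = 0.36, Fisher's exact test), and 1 rose in M6stop.

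Several of the largest falls in F9ΔNLS were also called in M6stop. CG12708 (-5.83), CG11241 (-3.72), dpr6 (-2.85), CG1208 (-2.84) and Ugt86Dc (-2.55) fell in F9ΔNLS in the authors' deposited table. CG7408 fell by 5.63 in F9ΔNLS (DESeq2 adjusted p = 1.4e-18) and had a log2 change of -1.46 in M6stop (DESeq2 adjusted p = 0.016) in the authors' deposited table. The noncoding CR45631 (-2.68) and the hexosaminidase gene Hexo2 (-2.12) fell in the authors' deposited table. The decarboxylase-like gene amd fell by 3.65 and the torsin-interacting protein gene TORIP (3L from 19803738 to 19805080) fell by 2.46 (DESeq2 adjusted p = 1.3e-103), with M6stop values of -0.06 and -0.02 that did not pass, in the authors' deposited table. The difference between the mutant lines was not tested.

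Histone genes fell broadly in F9ΔNLS. Of 23 tested copies 14 fell and 2 were called upward (adjusted p for falls = 8.5e-07, Fisher's exact test), with 14 and 2 adjusted over the list alone. His1:CG33822 (-1.46), His3:CG33821 (-1.34), His2B:CG33868 (-1.14) and His2A:CG33814 (-0.98) fell, and the list median was -0.62, in the authors' deposited table. The upward calls were His2B:CG33902 (listed value 0.01, DESeq2 adjusted p = 8.7e-06) and His4:CG33881 (0.04, DESeq2 adjusted p = 0.038) in the authors' deposited table, and these values do not give the size of the changes.

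Egg activation genes and meiotic recombination genes fell more often than other genes in F9ΔNLS. Of 14 egg activation and late oocyte genes 8 fell and 0 rose (adjusted p = 8.6e-04, Fisher's exact test), and at least 10 fell adjusted over the list alone. In the authors' deposited table dhd (-1.20), cort, an activator of protein degradation in female meiosis (-0.66), png, a kinase gene of the egg-to-embryo transition (-0.54), and the calcineurin gene CanB2 (-0.37) fell. Of 28 meiotic recombination and synapsis genes 11 fell and 1 rose (adjusted p = 0.0023, Fisher's exact test), with 11 and 1 adjusted over the list alone. They included c(3)G of the synaptonemal complex (-0.65), the kinesin genes nod (-0.57) and ncd (-0.53), and mus301 (-0.53) in the authors' deposited table.

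Eggshell genes did not move as a single group in F9ΔNLS. Of 13 vitelline membrane genes 7 fell and 3 rose (adjusted p for falls = 0.0028, Fisher's exact test), with 7 and 3 adjusted over the list alone. The membrane protein genes Vm26Ac (-1.62), Vm32E (-1.33), Vml (-1.10), Vm34Ca (-1.02) and Vm26Aa (-0.85) fell in the authors' deposited table. In contrast, fs(1)M3 (0.53), clos (0.55) and fs(1)N (0.29) rose in the authors' deposited table. Of 15 chorion genes 4 fell and 1 rose (adjusted p for falls = 0.36, Fisher's exact test). The eggshell gene dec-1 fell by 1.83 (DESeq2 adjusted p = 3.0e-04) in the authors' deposited table. Fcp3C (-0.16, DESeq2 adjusted p = 0.015), Cp7Fb (-0.11, DESeq2 adjusted p = 0.025) and Cp7Fc (-0.11, DESeq2 adjusted p = 0.020) fell as well in the authors' deposited table. The chorion genes Cp15 (-0.01), Cp36 (-0.06) and Cp38 (-0.05) did not pass in the authors' deposited table. Values appear to be shrunk, so these do not show that chorion RNA stayed level.

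Respiratory-chain and muscle genes rose in F9ΔNLS. Of 73 oxidative phosphorylation genes 31 rose and 0 fell (adjusted p = 1.1e-09, Fisher's exact test), and at least 40 rose adjusted over the list alone. COX7A (0.56), ATPsynD (0.40), ATPsynC (0.36) and ND-B16.6 (0.35) rose in the authors' deposited table. Of 26 muscle genes 13 rose and 0 fell (adjusted p = 2.9e-05, Fisher's exact test), and at least 15 rose adjusted over the list alone. The troponin gene TpnC73F (1.07), bt (0.95), Act57B (0.89) and the myosin heavy chain gene Mhc (0.81) rose in the authors' deposited table. Of 15 hemocyte markers 4 rose (adjusted p = 0.36, Fisher's exact test), namely Hml (3.09), Pxn (1.61) and the basement membrane collagen genes vkg (0.59) and Col4a1 (0.59), in the authors' deposited table. In M6stop 2 hemocyte markers rose, Hml (2.14) and Nplp2 (1.52), in the authors' deposited table.

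Follicle-cell and immune genes rose in F9ΔNLS as well. Of 27 follicle cell development genes 9 rose and 1 fell (adjusted p = 0.020, Fisher's exact test), with at least 9 upward and 2 downward adjusted over the list alone. They included Mmp2, a matrix metalloproteinase gene (1.31), the transcription factor genes mirr (0.61) and ct (0.40), and the adhesion gene Fas3 (0.48) in the authors' deposited table. Of 30 innate immunity genes 9 rose and 1 fell (adjusted p = 0.039, Fisher's exact test), with at least 10 upward and 1 downward adjusted over the list alone. Against random lists matched on mean count the immune list did not pass (adjusted p = 0.40, a permutation test). The antimicrobial peptide genes DptB (3.64), AttC (2.60) and Drs (2.39) and the recognition gene PGRP-SB1 (2.36) rose in the authors' deposited table. Means were low for DptB (9.35 normalized counts), PGRP-SB1 (13.1) and AttC (31.8), against 3697 for Drs, in the authors' deposited table. Of 19 fat-body markers 5 rose and 1 fell in F9ΔNLS, among them Fbp2 (2.74), Fbp1 (2.61), Lsd-1 (1.19) and FASN1 (0.50) upward in the authors' deposited table, and the list passed neither Fisher's exact test (adjusted p = 0.29) nor the permutation test with matched lists (adjusted p = 0.11). The fat body makes antimicrobial peptides too, so the tissue of the immune rise is not known. In M6stop 4 of the 30 rose, among them Drs (1.83) and PGRP-SB1 (2.11), in the authors' deposited table, and the list test did not pass (adjusted p = 0.14, Fisher's exact test).

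The remaining lists did not pass Fisher's exact test in F9ΔNLS, and several held genes that moved apart. Of 32 piRNA pathway genes 6 rose, among them qin (0.67), aub (0.44) and papi (0.43), and 6 fell, among them rhi (-0.76), in the authors' deposited table. Of 22 oocyte axis genes 6 rose and 2 fell, with orb (0.40) and sqd (0.35) upward and nos (-0.60) downward in the authors' deposited table. Of 19 stem cell and early cyst genes 5 rose and 2 fell, with Dad at 0.62 in the authors' deposited table. Of 17 heat shock genes 5 fell and 2 rose (adjusted p for falls = 0.25, Fisher's exact test), and the small heat shock protein genes Hsp26 (-1.03), Hsp23 (-1.03) and Hsp27 (-0.97) fell in the authors' deposited table. In M6stop 3 of the 17 rose (adjusted p = 0.14, Fisher's exact test), including Hsp70Bc (4.09), which has near-identical copies, in the authors' deposited table. Cytoplasmic ribosomal protein genes (0 of 88 rose and 2 fell), mitochondrial ribosomal protein genes (10 of 75 rose, and 1 in M6stop), glutathione S-transferase and P450 genes (9 of 87 rose and 10 fell), ecdysone genes (4 of 24 rose and 1 fell) and proteasome genes (1 of 32 rose and 2 fell) did not pass. Mitochondrial ribosomal protein genes passed against random lists matched on mean count in both lines, with medians of 0.02 in M6stop and 0.10 in F9ΔNLS in the authors' deposited table (adjusted p = 9.7e-04 and 0.0012, a permutation test).

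No other list passed Fisher's exact test in either line. Of 33 gut genes 1 was called in each line, Muc68D (-0.03 and -0.12, DESeq2 adjusted p = 1.4e-08 and 5.0e-06), in the authors' deposited table. Its listed values do not give the size of the changes. Gut genes were not all scarce: Mal-A1 had a mean of 8486 normalized counts, with uncalled values of -0.01 and -0.04, in the authors' deposited table. Since values appear to be shrunk, the few calls do not show that gut RNA stayed level. Of 8 tested testis genes 1 was called in each line, vis (2.26) in M6stop and twe (-0.44) in F9ΔNLS, in the authors' deposited table. The M6stop testis list, with a median of -0.06 in the authors' deposited table, passed against random lists matched on mean count (adjusted p = 0.0074, a permutation test). Of 22 genes of the m6A, cap and polymerase-tail machinery 1 fell in M6stop, and 3 fell and 1 rose in F9ΔNLS, with aft, a cap methyltransferase gene, down in both (-0.21 and -0.25) in the authors' deposited table. In F9ΔNLS 2 of 19 neuronal genes rose, 1 of 18 apoptosis genes rose and 2 fell, and 2 of 13 sex determination genes rose and 3 fell. DESeq2 gave 0 calls in M6stop for these 3 lists, with at least 2, 2 and 1 members at an unadjusted p under 0.05.

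**Figure D1:**
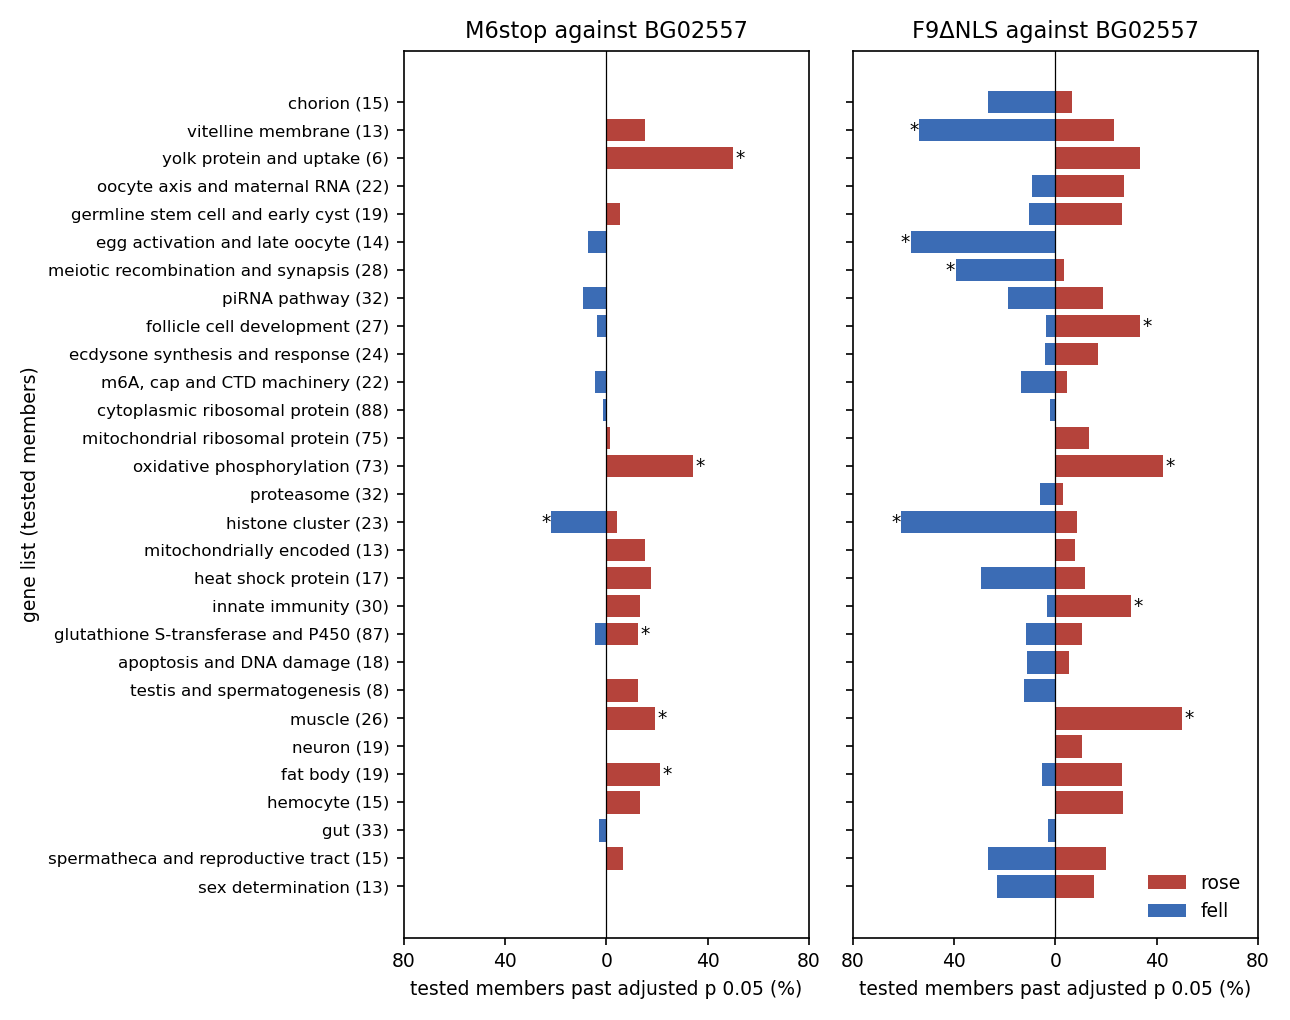
Share of tested members of each fixed gene list that rose (red, to the right) or fell (blue, to the left) against BG02557 at an adjusted p under 0.05 in the authors' deposited table, with the number of tested members in brackets and an asterisk where the one-sided Fisher's exact test of the list gave an adjusted p under 0.05. Oxidative phosphorylation genes rose in both lines (25 and 31 of 73), and histone genes fell in both (5 and 14 of 23).

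The last question was how far both mutant lines changed the same genes. Of the 589 genes called in M6stop, 380 were called in the same direction in F9ΔNLS, 240 upward and 140 downward. Independent lists of these sizes would share 42.9 and 25.8 genes. Both comparisons use the same control libraries, which alone makes their changes go together. In 1000 simulated sets of unchanged groups with a shared control and equal spread, the mean number called in both was 0.001 and the highest 1. With no changed gene almost none is called in either comparison, so this does not show how many of the shared calls come from the shared controls. The controls could not be split, so part of the excess may come from the shared controls. Both alleles were also made in another genetic background than the control line, which may give shared calls anywhere in the genome. Shared calls thus cannot be credited to Pcif1 alone.

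Across the 10662 tested genes, which are not independent replicates, the log2 fold changes of both lines had a Pearson r of 0.522 and a Spearman rho of 0.63. The simulated unchanged groups, of equal spread and without shrinkage, had a mean r of 0.50 and a highest r of 0.524. The Pearson r lies just under that highest value, but it was 0.56 for genes with a mean of at least 1 CPM and 0.63 for z values rebuilt from the adjusted p. Since the listed fold changes differ in spread between the lines, the simulation sets no firm bound for them. The rebuilt signed z values gave a covariance of 2.42 between the lines, against 0.50 in the simulation, a difference of 1.92. A covariance grows with the spread of the values, and the simulated ones held no changed gene to widen it. Rebuilt values are also bounds for tied genes. The difference therefore does not measure how much change the lines share.

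Of the genes called in both lines in the same direction, 107 changed by at least 1 in both, 73 upward and 34 downward. The largest shared changes were mostly in uncharacterized genes, and 8 of the top 10 lie on chromosome 3, which carries Pcif1. Its arms 3L and 3R hold 2045 and 2595 of the 10662 tested genes. CG14452 (3L from 22695953 to 22696435) had rises of 6.67 in M6stop and 7.12 in F9ΔNLS in the authors' deposited table, at a mean of only 12.7 normalized counts. In the same order, the authors' deposited table gave rises of 6.08 and 5.29 for CG42833, 5.56 and 5.96 for CG32212, 5.01 and 5.56 for the ionotropic receptor gene Ir85a, and 3.79 and 4.82 for the fucosyltransferase gene FucTA. CG15646, close to CG12708 on the X chromosome, fell in both (-5.22 and -5.58) in the authors' deposited table. CG12708, CG4570, CG2993 and CG11241, given above, complete the top 10. Other means were low too, with 8.62 normalized counts for CG15646, 15.3 for Ir85a, 38.4 for FucTA, 44.4 for CG32212 and 46.7 for CG42833 in the authors' deposited table, and CG32212 overlaps the hairpin RNA gene hpRNA:CR33940 on the other strand, so its value is uncertain. CG32212, CG42833, CG14452 and CG11241 lie within 5 Mb of Pcif1, as do 669 of the 10577 tested genes with a position. The shared changes of these 4 genes may come from sequence linked to the alleles rather than from Pcif1. For the other shared changes, such as those of CG12708 and CG15646 on the X chromosome, remaining background cannot be told apart from Pcif1 either.

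Only 5 genes were called in opposite directions, and each of them rose in M6stop and fell in F9ΔNLS. They were the hairpin RNA gene hpRNA:CR32207 (1.20 and -0.77), the eggshell gene psd (0.63 and -0.78), CG8303 (0.55 and -0.52), the centriole gene ana2 (0.36 and -0.40) and CG6770 (0.20 and -0.18), all in the authors' deposited table. These 5 were named after their values were seen. M6stop and F9ΔNLS were not tested against each other.

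**Figure D2:**
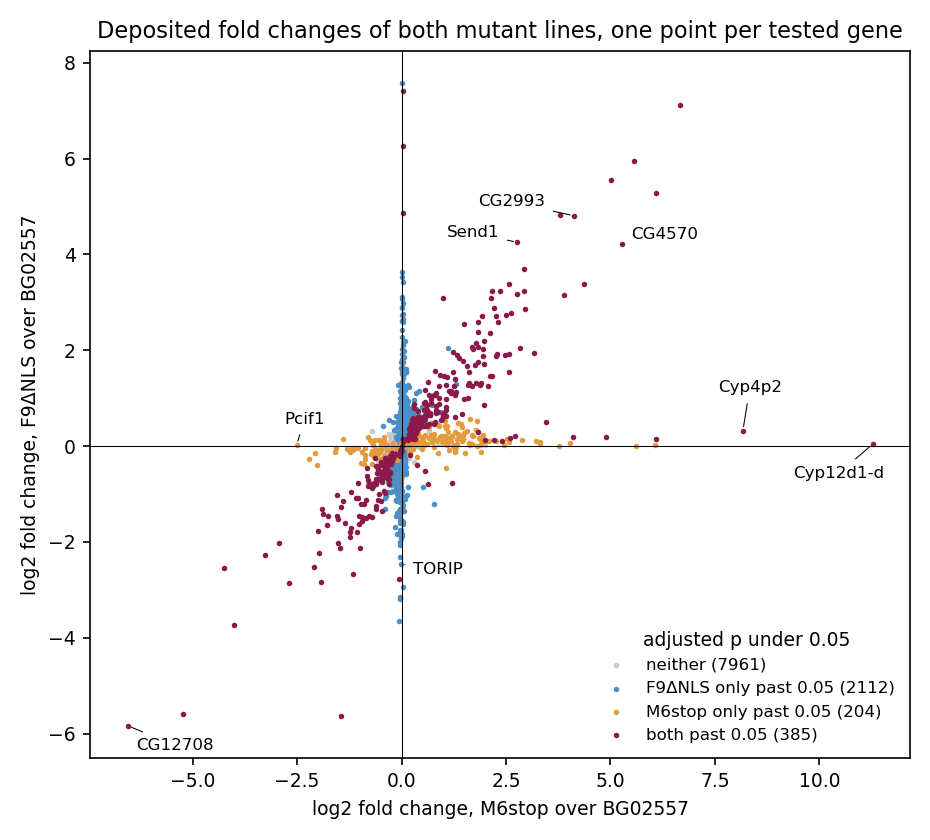
Log2 fold change over BG02557 of each of the 10662 tested genes in M6stop (horizontal axis) and F9ΔNLS (vertical axis), from the authors' deposited table, with colours for the comparison in which the adjusted p was under 0.05. Pcif1 sits at -2.51 in M6stop and 0.02 in F9ΔNLS, and 380 of the 385 genes called in both lines have changes of the same sign.

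Both alleles were made in another genetic background than the control line and then backcrossed to it for up to 10 generations, so calls were also counted around Pcif1 on chromosome arm 3L. Within 5 Mb of Pcif1, 60 of 669 tested genes (8.97%) were called in M6stop, against 5.30% of tested genes elsewhere (odds ratio 1.76, 95% interval 1.31 to 2.34, p = 1.6e-04, two-sided Fisher's exact test). In F9ΔNLS 183 of the 669 (27.4%) were called, against 23.1% elsewhere (odds ratio 1.252, 95% interval 1.04 to 1.497, p = 0.014, two-sided Fisher's exact test). Within 1 Mb the F9ΔNLS odds ratio was 1.23 (p = 0.20, two-sided Fisher's exact test). Genes near Pcif1 called in both lines, chosen after their values were seen, included AcCoAS, an acetyl-CoA synthetase gene (0.83 and 0.74), S1P, a protease gene (-0.71 and -0.87), Cyp305a1 (-1.39 and -1.14) and olf413 (2.49 and 2.73), all in the authors' deposited table. Other genes near Pcif1 were called in a single line, among them TORIP (-0.02 and -2.46), with Atox1 (-1.31 and -0.06) and CG13813 (0.03 and -2.93) also chosen later, in the authors' deposited table. The mean of CG13813 was 32.7 normalized counts in the authors' deposited table. Neighbouring genes are not independent, so these p-values may be too small.

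**Figure D3:**
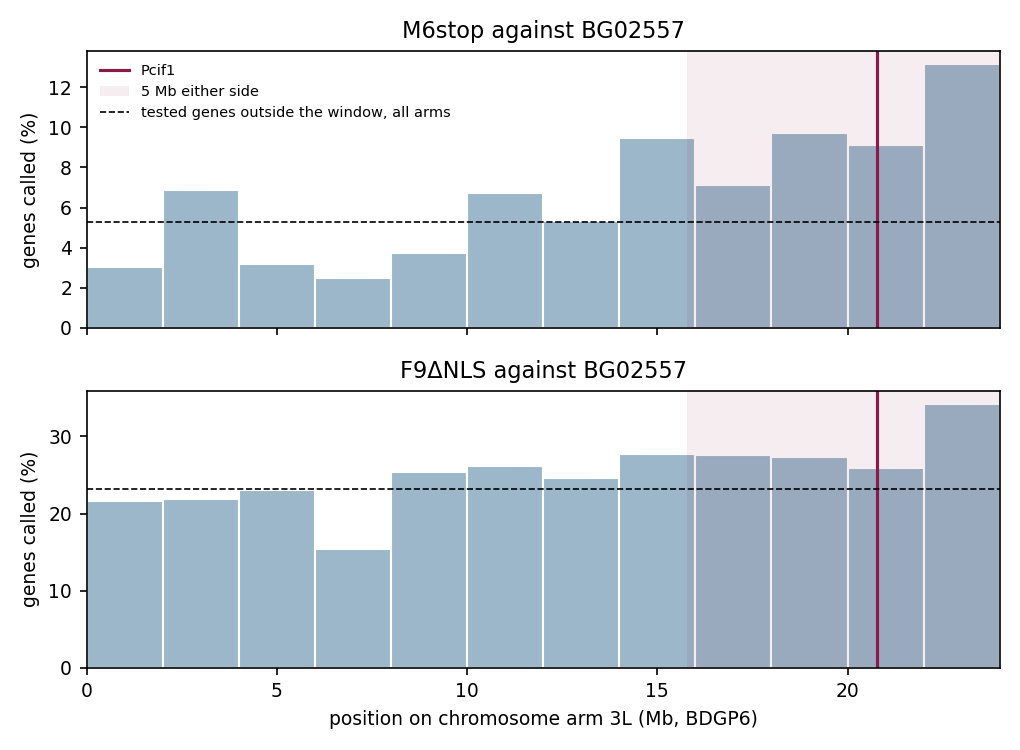
Share of tested genes called in each 2 Mb stretch of chromosome arm 3L (bars, with position in Mb of BDGP6 on the horizontal axis and stretches of under 20 tested genes left out) in M6stop (top) and F9ΔNLS (bottom). The red line marks Pcif1, the shaded area 5 Mb either side of it, and the dashed line the share among tested genes outside that area on all arms (5.30% and 23.1%).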

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

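Only alternatives that need no library values could be run. The thresholds of 0.01 and 0.1 for gene counts, the protein-coding subset, the removal of calls under 0.1 in absolute log2 change, the rank and z correlations and the matched random lists were chosen after seeing the data; the 0.01 threshold near Pcif1 was set before. Requiring a log2 change of at least 1 left 206 genes in M6stop (157 up), 270 in F9ΔNLS (164 up) and 107 in both. That moved the share of rises from 63.0% to 76.2% in M6stop and from 49.4% to 60.7% in F9ΔNLS. An adjusted p under 0.01 left 351, 1495 and 222 genes. The lines thus had 2497 against 589 calls, but 270 against 206 of at least 1. Fewer genes pass by construction, limits on fold change act on values that appear to be shrunk, and the causes of the other moves were not tested. The correlation of fold changes was 0.56 with a mean of at least 1 CPM, 0.63 by ranks and 0.63 for rebuilt z values. The number of lists called went from 6 to 11 in M6stop under matched random lists, and was 8 under both tests in F9ΔNLS. Under the matched lists the M6stop glutathione S-transferase and P450 list, the M6stop fat-body list and the F9ΔNLS immune list no longer passed (adjusted p = 0.13, 0.90 and 0.40, a permutation test). Gained were vitelline membrane, egg activation, both ribosomal protein lists, proteasome, mitochondrially encoded and testis genes in M6stop, and mitochondrial ribosomal protein genes in F9ΔNLS. The F9ΔNLS odds ratio near Pcif1 was 1.23 within 1 Mb and no longer passed (p = 0.20, Fisher's exact test), with fewer genes in the window. For calls at an adjusted p under 0.01 within 5 Mb it was 1.24 and barely passed (p = 0.04999, Fisher's exact test). Its 95% interval of 0.996 to 1.54 included 1. Of 31 alternative values 20 stayed (counts within 1.5 times, odds ratios with the same call, correlations inside the 95% interval of 0.508 to 0.536), 10 moved, among them all 3 correlations, 1 lost its call and 0 reversed. Counts with a mean of at least 1 CPM, with an adjusted p under 0.1, for protein-coding genes and without calls under 0.1 all stayed within 1.5 times.

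No paired analysis was possible because the library columns carry no replicate number and were tied to no sample. For the same reason other normalizations, DESeq2, other filters inside a fit, fits on 6 libraries, leaving out single libraries, pseudocounts, other splits of the libraries, fry and camera were not run, and no result can be said to be stable against the loss of one library. The depth of single libraries was not used, so how far depth limits the genes with low means was not tested.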

Other observations

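The tests of muscle markers, histone types, symbol families and runs of neighbouring genes were chosen after the results were seen. The window around Pcif1 was set before the data were examined. The replication gene list was written after Orc and Mcm genes were seen to fall but before its own members' values were looked up.

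DNA replication genes fell in F9ΔNLS. Among all 134 families of protein-coding genes that share a symbol stem (536 one-sided Fisher's exact tests with Benjamini-Hochberg adjustment, 7 of which passed), the origin recognition complex genes Orc1 to Orc6 fell in F9ΔNLS (6 of 6, adjusted p = 7.2e-04, Fisher's exact test), from -0.46 for Orc6 to -0.81 for Orc5 in the authors' deposited table. Of 6 Mcm genes 5 fell (adjusted p = 0.013, Fisher's exact test), including the replicative helicase genes Mcm5 (-0.69) and Mcm3 (-0.57) in the authors' deposited table. In M6stop DESeq2 called 0 of the 6 Orc genes and 1 of the 6 Mcm genes, Mcm5 (-0.31 in the authors' deposited table). Translation initiation factor genes rose in F9ΔNLS, 12 of 36 (adjusted p = 0.037, Fisher's exact test), among them eIF4G1 (0.55), eIF4H1 (0.50) and eIF5B (0.43) in the authors' deposited table. The stem l(1)G passed in F9ΔNLS as well (5 of 7 rose, adjusted p = 0.031, Fisher's exact test), and a shared stem need not mean a shared function. In M6stop vacuolar proton pump genes rose, 6 of 14 (adjusted p = 7.2e-04, Fisher's exact test), including Vha100-2 (0.29), Vha55 (0.34) and Vha16-1 (0.40) in the authors' deposited table, and 2 of the 14 rose in F9ΔNLS. The precursor ribosomal RNA gene pre-rRNA:CR45847 rose by 0.74 in F9ΔNLS (DESeq2 adjusted p = 2.4e-07) and had a value of 0.27 in M6stop (DESeq2 adjusted p = 0.083) in the authors' deposited table. The 28S gene 28SrRNA:CR45844 had values of 0.09 in M6stop and -0.09 in F9ΔNLS in the authors' deposited table, neither past the threshold, and the depletion of ribosomal RNA acts on these levels.

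The histone fall in F9ΔNLS could come from reads moving between near-identical copies, or from fewer replicating cells. Reads that only moved among the tested copies would leave some histone type near 0 when its copies are weighted by abundance. The least changed type, His2A, had a weighted mean of -0.64 and the most changed, His3, one of -0.96, each over 2 tested copies. Only 23 of the 31 listed copies were tested, and the listed values appear to be shrunk, which can hide gains. The weighted means therefore cannot exclude moved reads. Of 34 tested genes of the replication list, which holds no Orc or Mcm gene, 23 fell and 1 rose in F9ΔNLS (67.6% fell against 11.9% of all tested genes, p = 3.3e-14, one-sided Fisher's exact test), as a smaller share of replicating cells would need; the p treats co-regulated genes as independent. In M6stop, where 5 of 23 histone copies fell and the weighted means of the types ran from -0.17 to -0.41, 0 of the 34 replication genes were called, but 33 had negative values, with a median of -0.09 in the authors' deposited table against -0.0007 for all tested genes. A lower level per cell and a different mix of egg chamber stages stay open, and the mutant lines were not tested against each other.

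The rise of respiratory-chain genes may come from more muscle tissue in the mutant preparations, since muscle genes rose too. Extra muscle would raise its own markers by more than genes that every ovary cell uses. In F9ΔNLS the median muscle marker with a mean of at least 50 lay 0.40 above the median respiratory-chain gene (bootstrap 95% interval 0.20 to 0.55), which does not exclude extra muscle, but the medians of both lists had been seen before, so this gives it no separate support. In M6stop the difference was -0.043 (interval -0.11 to 0.28), so muscle and a change within ovary cells cannot be told apart there, because the interval spans 0. Both intervals come from resampling genes as independent draws. They carry no spread between libraries and may be too narrow for co-regulated genes. A change in the mitochondria of ovary cells was not tested.

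The excess of calls around Pcif1 may come from sequence of the edited background that stayed linked to the alleles. The odds ratios of 1.76 in M6stop and 1.252 in F9ΔNLS had to exceed 1 for this, but they measure the clustering itself and so do not favour linked background over another cause. Of 647 overlapping runs of 669 neighbouring genes outside the window, 32 (4.95%) held as high a share of M6stop calls and 22 (3.40%) as high a share of F9ΔNLS calls, all of them on 3R between 0.57 and 14.3 Mb. Since 3R is the other arm of the chromosome that carries Pcif1, linked sequence may raise these runs too. They therefore do not count against linked sequence. On X, 2L and 2R 0 of 387 runs were as high, but these amount to only 8 separate ones (14 with chromosome 3). Chromosome 4, with 90 tested genes, is too short for such a run. There 11.1% of genes were called in M6stop and 31.1% in F9ΔNLS, above the shares near Pcif1. Neither share differed from that of the other genes after adjustment (adjusted p = 0.16 and 0.21, Fisher's exact test). A block special to Pcif1 and clustering elsewhere thus cannot be told apart. None of 62 stretches of 2 Mb passed by Fisher's exact test after adjustment in either line, with the lowest adjusted p, 0.056, for 3R from 10 to 12 Mb in M6stop, and genotypes of the lines were not analysed here.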
